A study of Mus musculus with 5 samples.

How the data were processed

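The deposited files hold, for each of 5 tumor libraries, a matrix of whole-number UMI counts over 32285 genes and 12 antibody tags, with no filter on cells. Per the file headers these counts were made with Cell Ranger 7.1.0, and the submitters' processing notes name bcl2fastq, Cell Ranger and the mm10 build. The annotation release is not given in the sources used here. The matrices list 730926 barcodes in Control, 730266 in MSA-2, 734280 in IPI-549, 730680 in SH-273 and 732325 in Nano-273. Cells took 94.7%, 95.0%, 96.5%, 95.9% and 92.3% of the gene UMIs in the same order. Antibody UMIs were 39932968, 49969267, 54048625, 58370664 and 56638840 and were left out of all gene totals. The labels name a chemistry that reads the 3′ end. The number of listed barcodes and the frequent reads over antibody variable genes look like a 5′ kit. Results on antibody variable genes depend on the end that was read, and no other statement rests on it. The labels also speak of nuclei beside cell suspensions stained on the surface. Whether cells or nuclei were captured is open for the UMI and mitochondrial values. Each group has 1 library, and groups follow the treatment label.

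Comparisons, gene lists, cell type markers, filters, the rule for named genes and 33 alternatives were fixed before the data were examined. A barcode was kept as a cell with at least 500 gene UMIs, at least 300 genes and at most 15% mitochondrial UMIs. The mitochondrial limit removed 101, 50, 43, 38 and 38 barcodes in the order above. Doublets were called in each library by Scrublet (scanpy 1.11.5, expected rate 0.06, automatic threshold). It removed 69 cells in Control, 40 in MSA-2, 4 in IPI-549 and 314 in Nano-273. In SH-273 it marked 0 of 9497 cells, which is taken as not having worked, so no doublets were removed there, and 4 of 4569 in IPI-549 is close to none.

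Cells of all libraries were clustered together without batch integration. Counts were scaled to 10000 UMIs per cell and log transformed, and 2000 variable genes gave 30 principal components. Mitochondrial, ribosomal, haemoglobin and antigen receptor variable genes were left out of these genes. A graph of 15 neighbours was split by the Leiden method at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9). Clusters were named among 20 cell classes where at least 3 markers were detected. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.

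Several rules were set after the clusters had been seen. Naming of clusters was tried with 2 rules, because the first, the fold over all other cells, left the high-RNA B-like cells without a name, and the fold over the median cluster is used. B-like clusters were split into resting and high-RNA cells at a cluster median of 10000 UMIs. Clusters with a median doublet score of at least 0.15 were set aside, which took 25 cells (0.404%) in Control, 61 (1.01%) in MSA-2, 35 (0.767%) in IPI-549, 344 (3.62%) in SH-273 and 220 (2.17%) in Nano-273. Clusters without a name held 0.905%, 4.22%, 0.613%, 0.737% and 2.16% of cells. Subsets inside the B-like, T-like and macrophage-like classes were also named with the second of 2 rules, a mean marker fold of at least 2 and no more markers of another type than of its own. T-like cells without the naive clusters, neutrophil-like cells without the blood-type clusters (led by Retnlg or Camp) and macrophage-like cells of the C1q clusters were taken apart after the whole classes had been seen. Il10 was among the 10 leading genes of high-RNA B-like clusters, so the clustering was run again without it, and 40 of 40 class shares stayed the same.

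Shares of cells have exact Clopper-Pearson 95% intervals, CPM values exact Poisson intervals, and ratios of CPM exact intervals from the binomial split of both counts. All of them cover counting error only and say nothing about the spread between animals. The intervals of CPM values and of their ratios also leave out the spread between cells of a library. The denominator of immune shares is all cells in clusters named as leukocytes. A class was compared where both libraries held at least 50 of its cells. Log2 ratios carry a pseudocount of 5 CPM on both sides and the ratio intervals none, so a ratio of weakly expressed genes can lie outside its interval; CPM values are printed where this matters. For a gene with 0 counts a bound is given from 3 counts. There were 7 comparisons, 4 of them with Control. No test between groups was run, and the planned counts of genes at 2-fold are not printed, because with 1 library per group such a count has no error.

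For 31 gene lists the median log2 ratio over members with at least 20 UMIs was taken where at least 5 were measured. Its percentile among 10000 random lists of the same size, matched on mean CPM in 20 bins, describes these libraries only, since the genes of a list are not independent. Named genes are the 3 highest and 3 lowest log2 ratios among genes with at least 100 CPM and 50 UMIs in the higher library and a level no lower than in its empty droplets, those with fewer than 100 UMIs. Ribosomal, mitochondrial, haemoglobin, antigen receptor and sex-linked genes, unnamed transcripts and markers of other classes were left out. Il10, Ebi3, Pik3cg and Tmem173 were named in any case. Other members of the lists are given as examples that were chosen after their values were seen. Doublet calls, depth and free RNA were handled as alternatives, which include thinning every cell to 1000 or 2000 UMIs. The 99th percentile calling kept barcodes with at least 10% of the 99th percentile of depth among the 5000 deepest. Its cuts were 7227, 7876, 7841, 7566 and 6623 UMIs in Control, MSA-2, IPI-549, SH-273 and Nano-273. Neutrophil-like, T-like, resting B-like and macrophage-like cells had medians below these cuts, so it left out most of them. A few results for single genes and tags are not reported here. After the data had been seen 10 more alternatives were added.

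The ratio and list methods were tested on simulated data made from the summed counts by drawing molecules at known ratios. In epithelial-like cells of MSA-2 and Control, with 15452 genes, 95.4% of intervals of unchanged genes held the true ratio. A simulated 2-fold difference gave a median log2 ratio of −0.95 or 0.96 at 50 CPM and more, and the pseudocount shrank it at lower levels. Random lists fell outside the central 95% in 4.5% of draws. The draws followed the counting model that the intervals assume, with independent genes. They check the calculation alone and do not show that the intervals hold for real cells.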

Results

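Single-cell RNA profiles were made from tumors of mice bearing KPC tumors, a mouse model of pancreatic cancer. There were 5 libraries, 1 for each of 5 groups, which were an untreated Control, MSA-2, IPI-549, SH-273 and Nano-273. MSA-2 is a non-nucleotide agonist of STING, the receptor for cyclic dinucleotides that turns on interferon genes, and IPI-549 inhibits PI3Kγ, a lipid kinase of leukocytes. The series title speaks of targeting both proteins at once, of regulatory B cells and of resistance to STING agonists. SH-273 is read here as the compound aimed at both targets and Nano-273 as its nano-formulation, which the labels do not spell out. Tumors were collected 9 days after the last dose, and the doses are not given in the sources used here. Dead cells were removed and the cells were stained with 12 antibody tags before capture.

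The gene counts of the libraries were 114062641 UMIs (unique molecules) in Control, 114002743 in MSA-2, 60795508 in IPI-549, 117143763 in SH-273 and 134368614 in Nano-273. After filtering, 6189 cells were kept in Control, 6023 in MSA-2, 4565 in IPI-549, 9497 in SH-273 and 10161 in Nano-273. The median cell held 12593, 10954, 4170, 4103 and 5509 UMIs in the same order. With 1 library per group there is no replicate error, so no difference between groups was tested. All intervals are 95% intervals of counting error alone, and log2 ratios compare UMI counts summed over the cells of a class and scaled to the class total (CPM). Each library may hold 1 tumor or a pool, which the labels do not say. Clusters were named from marker genes, so every cell type is meant as "like" that type.

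B-like cells formed 2 blocks that differed in RNA content. Resting B-like cells had small RNA contents, with a median between 1874 and 2843 UMIs per cell across the libraries. High-RNA B-like cells had medians of 22886 UMIs in Control, 25627 in MSA-2, 19779 in SH-273 and 17526 in Nano-273. The 5 cells of IPI-549 in these clusters had a median of 3024, near the 2843 of its resting B-like cells. The B identity of the high-RNA cells had support from an antibody tag. The median B220 tag count was 84 in the high-RNA cells and 28 in epithelial-like cells of Control, and 152 against 49 in Nano-273. A class given to each cell from its own markers did not bear this out for most of them, since 11.2% of all 10668 high-RNA cells scored as high-RNA B-like, 2.28% as resting B-like and 12.5% as plasma-like, against 20.9% as mesothelial-like, 15.99% as erythroid-like and 13.1% as mature dendritic-like. Naming of the high-RNA cells was fragile, because with doublets kept, a mitochondrial limit of 10% or a resolution of 0.5 their clusters had no name and their share was 0.

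The first question is which cells made up each tumor. Immune cells were 57.7% of kept cells in Control, 77.7% in MSA-2, 66.5% in IPI-549, 83.4% in SH-273 and 89.5% in Nano-273. Epithelial-like cells, the class that holds the tumor cells, were 36.3% (35.1 to 37.6) of kept cells in Control. They were 13.9% (13.03 to 14.8) in MSA-2, 29.0% (27.7 to 30.3) in IPI-549, 10.1% (9.47 to 10.7) in SH-273 and 4.85% (4.44 to 5.29) in Nano-273. Fibroblast-like cells were 4.28% in Control, 2.92% in MSA-2, 3.001% in IPI-549, 2.001% in SH-273 and 1.27% in Nano-273. A sum of shares is fixed, so a larger lymphocyte share lowers all other shares without any change in their number.

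**Figure D1:**
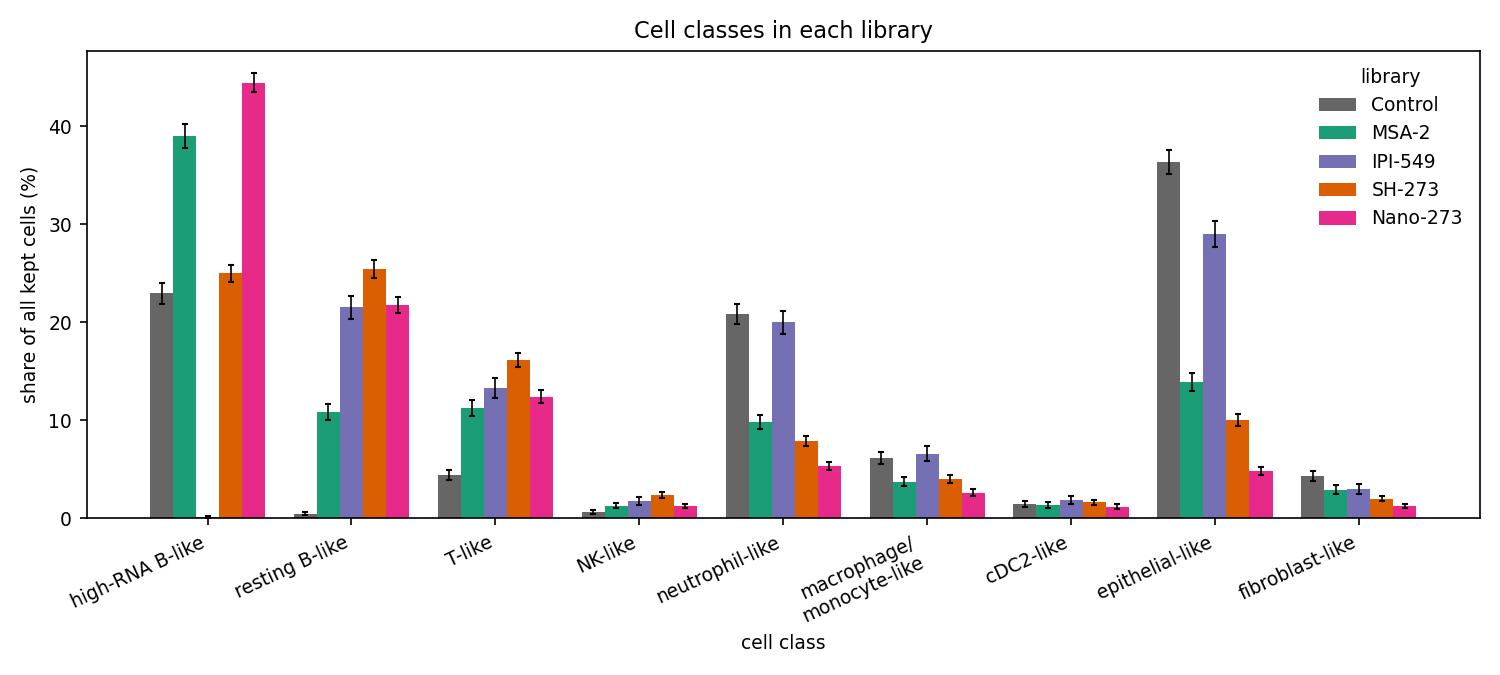
Bars give the share of all kept cells (percent, vertical axis) taken by 9 cell classes (horizontal axis) in the 5 libraries, and error bars are 95% Clopper-Pearson intervals of counting error. High-RNA B-like cells took 22.96% of Control, 39.0% of MSA-2, 0.110% of IPI-549, 25.01% of SH-273 and 44.5% of Nano-273, and epithelial-like cells were lowest in Nano-273 at 4.85%.

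The comparison of MSA-2 with Control asks what a STING agonist alone left behind in the tumor. The MSA-2 library held more B-like and T-like cells and fewer neutrophil-like, macrophage-like and epithelial-like cells than Control. Its epithelial-like and stromal cells carried more antigen presentation and interferon gamma response transcripts. Its T-like cells outside the naive clusters carried more cytotoxic and fewer regulatory T transcripts. The high-RNA B-like cells kept the Il10 level of Control, where Il10 is the cytokine by which regulatory B cells are mostly recognised.

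High-RNA B-like cells were 39.8% (38.2 to 41.4) of immune cells in Control and 50.2% (48.7 to 51.6) in MSA-2. Resting B-like cells were 0.812% (0.545 to 1.16) in Control and 13.95% (12.97 to 14.98) in MSA-2, and T-like cells 7.68% (6.82 to 8.60) and 14.4% (13.4 to 15.5). The T-like direction turned with the 99th percentile calling, to 1.88% in MSA-2 against 2.84% in Control. That depth cut leaves out most T-like cells. Neutrophil-like cells were 36.2% (34.6 to 37.8) of immune cells in Control and 12.6% (11.7 to 13.6) in MSA-2, and macrophage/monocyte-like cells 10.6% (9.62 to 11.7) and 4.79% (4.19 to 5.44).

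In high-RNA B-like cells Il10 stood at 232.9 CPM (228.0 to 237.9) in Control and 234.3 CPM (230.7 to 238.0) in MSA-2. Il10 UMIs were found in 72.9% of these cells in Control and 72.6% in MSA-2. In epithelial-like cells, which should lack the gene and were as deep at medians of 22442 and 29626 UMIs, the shares were 1.24% and 1.43%. Ebi3, the subunit shared by interleukins 27 and 35, was at 88.1 CPM (85.1 to 91.2) and 89.1 CPM (86.8 to 91.4). The regulatory B list had a median log2 ratio of 0.00, with 9 of 18 measured genes higher in MSA-2. Sting1 (Tmem173 in the files) was at 12.99 CPM in Control and 12.4 CPM in MSA-2, and Pik3cg, the catalytic subunit of PI3Kγ, at 18.01 and 19.8 CPM. Among genes that met the rule for named genes, the differences in these cells were small. The highest were Mt1, a metallothionein, at log2 0.52, the glycolytic enzyme Gapdh at 0.36 and Bcl2a1d at 0.32. On the low side were Nfkbid at −0.19, Ap2s1 at −0.14 and Txnrd1 at −0.13. Genes outside that rule could lie further apart. Jchain, which joins the chains of secreted IgM and IgA, had a log2 ratio of −0.75 that became 1.13 with a minimum of 1000 UMIs and 500 genes per cell.

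In epithelial-like cells all 14 measured MHC class I presentation genes were higher in MSA-2, with a median log2 ratio of 1.07 that lay above all 10000 random lists. H2-K1 was at 1039 CPM against 324.8 in Control (log2 1.66), H2-D1 at 817.3 against 289.1 (log2 1.48), and the immunoproteasome subunit Psmb8 had a log2 ratio of 2.21. Of 26 measured interferon gamma response genes, 26 were higher, with a median of 1.05. Among them the GTPase Gbp2 was at log2 1.79 and the T cell attractant Cxcl9 at 1.68. Psmb8, Psmb9, Psmb10, Tap1 and Tapbp belong to both the class I and the interferon gamma list. MHC class II presentation had a median of 1.13, with 10 of 11 genes higher and Cd74, the class II invariant chain, at log2 1.61. The type I interferon response was less apart, with a median of 0.23 and 25 of 31 genes higher, while Isg15 was at −0.15 and Ifit1 at −0.39. The sign of Isg15 turned to 0.08 with doublets kept. The trefoil factors Tff1 and Tff2, products of gastric-type mucous cells, had log2 ratios of −1.48 and −1.26, and the scavenger protein Dmbt1 −1.05. The largest epithelial-like cluster differed between these 2 libraries. Dissociation stress genes had a median of −0.40 in these cells, with 3 of 18 higher, and the immediate early gene Dusp1 was at −0.86.

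In fibroblast-like cells 14 of 14 MHC class I genes were higher with a median of 0.75, and the interferon gamma list had a median of 0.56. The myofibroblastic list had a median of −0.51 with 1 of 12 genes higher, and its member Tagln, a smooth muscle actin binding protein, was at −1.01. Dlk1, a membrane protein related to Notch ligands, stood at 313.7 CPM against 53.2 in Control (log2 2.45), and the chemokine Ccl2 was at −1.65.

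T-like cells without the naive clusters had 16 of 18 T cytotoxicity genes higher in MSA-2, with a median of 1.27. Gzma and Gzmb, granule proteases of killer cells, had log2 ratios of 2.59 and 1.47, and the chemokine Ccl5 stood at 8922 CPM against 2470 (log2 1.85). All 11 measured regulatory T genes were lower, with a median of −1.25, and Foxp3, their lineage factor, was at −1.55. A cluster led by Nkg7, Gzma and Cd8b1 held 280 of 399 of these cells in MSA-2 and 85 of 238 in Control. A cluster led by Tnfrsf4 and Ikzf2, with regulatory T-like and other CD4-like cells, held 77 in MSA-2 and 116 in Control. The lists therefore follow the mix of clusters, and levels within a cluster were not compared. Ifng itself was at −0.05.

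C1q macrophage-like cells had 19 of 23 interferon gamma response genes higher, with a median of 0.56. Their Cxcl9 stood at 333.1 CPM against 55.4 (log2 2.49) and their Ccl5 at log2 4.21. Cd163 and Lyve1, receptors of tissue-resident macrophages, were at −2.75 and −2.42. Across the whole macrophage/monocyte class Ly6c2, a marker of blood monocytes, was at 174.8 CPM against 41.5. Neutrophil-like cells outside the blood-type clusters had interferon gamma and type I medians of 0.92 and 0.65, with Gbp2 at log2 2.21 and Isg15 at 1.67. None of their 16 hypoxia and glycolysis genes was higher, with a median of −0.61, and Adm, a hypoxia-induced peptide, was at −1.73. The cDC2-like cells had a median of 0.81 for the interferon gamma list and Cxcl9 at log2 3.23. Depth limits the macrophage and cDC2 values, which rest on 169 and 83 cells in MSA-2.

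The comparison of IPI-549 with Control asks what PI3Kγ inhibition alone did. The high-RNA B-like block was nearly missing from this library, and its B-like cells were resting cells. Neutrophil-like, macrophage-like and epithelial-like shares stayed nearer to Control than in the other treated libraries, in part because the high-RNA block counts in the Control total. The antigen presentation and interferon gamma lists were at or slightly under the Control level in epithelial-like, fibroblast-like and C1q macrophage-like cells.

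High-RNA B-like cells were 5 of 3036 immune cells, a share of 0.165% (0.0535 to 0.384), against 39.8% in Control. Resting B-like cells were 32.3% (30.7 to 34.0) and T-like cells 19.99% (18.6 to 21.5) of immune cells. Neutrophil-like cells were 30.1% (28.4 to 31.7) and macrophage/monocyte-like cells 9.91% (8.87 to 11.03). Among immune cells without the high-RNA block, neutrophil-like cells were 60.1% in Control, 25.3% in MSA-2 and 30.1% in IPI-549, and macrophage/monocyte-like cells 17.6%, 9.61% and 9.93%. With 5 cells the high-RNA block was not compared gene by gene, and the whole B-like class shows the exchange of 1 block for the other. Il10 had 0 UMIs in all B-like cells of IPI-549, at least 252.9-fold below the 232.6 CPM of Control, and Ebi3 was at 17.5 against 88.0 CPM. Zbtb32, a repressor found in activated B cells, was at 2.45 against 413.4 CPM and Rgcc at log2 −5.54. The highest ratios belonged to genes of resting B cells, with the lymphotoxin subunit Ltb at 1071 against 2.04 CPM, the IgE receptor Fcer2a at log2 5.98 and Fcrla at 5.56. The B naive follicular list had a median of 3.49, with 12 of 12 genes higher.

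In epithelial-like cells of IPI-549 the MHC class I list had a median of −0.20 with 1 of 14 genes higher, and the interferon gamma list −0.16 with 4 of 25 higher. H2-K1 was at log2 −0.35, Psmb8 at −0.43 and Cxcl9 at −0.27. The MHC class II list had a median of −0.16 with 5 of 12 genes higher, and the type I list one of −0.04. Dissociation stress genes were as low, with a median of −0.20 and 1 of 18 higher. Under the rule for named genes the 3 highest were all small subunits of mitochondrial complexes, Ndufb1-ps at 105.3 against 65.1 CPM, Ndufa3 at log2 0.65 and Atp5mpl at 0.62. Ndufb1-ps was also highest in IPI-549 in resting B-like, neutrophil-like, C1q macrophage-like and fibroblast-like cells. Ifit1 was at −0.36, a sign that turned to 0.80 when each cell was thinned to 1000 UMIs.

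T-like cells without the naive clusters had a cytotoxicity median of −0.21 and a regulatory T median of −0.01, and 150 of 231 lay in the cluster of regulatory T-like and other CD4-like cells. Ifng stood at 69.7 against 187.5 CPM (log2 −1.37), the checkpoint receptor Lag3 at −1.31 and the cytokine Csf2 at −1.71. Gzma was higher at 1.16 and Gzmk lower at −0.93. The T exhaustion list had a median of −0.42. In C1q macrophage-like cells the protease Ctsk stood at 171.1 against 5.92 CPM (log2 4.01), the bridging protein Mfge8 at −1.28 and Lyve1 at −1.24, and the interferon gamma list had a median of −0.04. Neutrophil-like cells outside the blood-type clusters had medians of 0.05 for interferon gamma and 0.16 for type I. In fibroblast-like cells the acute phase protein Saa3 was at −1.49, Sfrp4, a Wnt-binding protein, at 1.11 and the myofibroblastic list at −0.18. The fibroblast values rest on 137 cells. The 99th percentile calling turned the epithelial-like share to 72.4% against 49.6% in Control. That depth cut leaves out most neutrophil-like, T-like and resting B-like cells.

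The comparison of SH-273 with Control asks what the compound meant for both targets left behind. High-RNA B-like cells were a smaller share of immune cells than in Control, though not of all kept cells, and their Il10 and several other regulatory B genes were much lower. Epithelial-like and stromal cells carried more antigen presentation transcripts, as in the MSA-2 library. T-like cells outside the naive clusters had more cytotoxic and fewer regulatory T transcripts, beside another mix of clusters. Resting B-like and naive T-like cells were abundant.

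High-RNA B-like cells were 29.99% (29.0 to 31.01) of immune cells, against 39.8% in Control, and resting B-like cells 30.5% (29.5 to 31.5) against 0.812%. Of all kept cells the high-RNA block was 25.01% in SH-273 and 22.96% in Control. T-like cells were 19.4% (18.5 to 20.2), neutrophil-like cells 9.46% (8.82 to 10.1) and macrophage/monocyte-like cells 4.82% (4.36 to 5.32). The 99th percentile calling gave the high-RNA block 74.6% of immune cells in SH-273 against 43.8% in Control. That depth cut leaves out most resting B-like, T-like and neutrophil-like cells. A class per cell from markers gave 5.63% against 4.79%. Both turn the direction.

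In high-RNA B-like cells Il10 was at 23.5 CPM (22.3 to 24.8) in SH-273 against 232.9 CPM in Control, a log2 ratio of −3.06. Il10 UMIs were found in 21.3% of these cells against 72.9%, and in 0.941% of epithelial-like cells of SH-273, whose median depth was 26562 UMIs against 19779 in the B-like cells. With every cell thinned to 1000 UMIs the shares were 1.99% (1.46 to 2.63) in SH-273 and 17% (15.1 to 19.1) in Control, and none of the thinned epithelial-like cells of SH-273 had a UMI. Ebi3 was at 45.5 CPM (43.8 to 47.3) against 88.1. The regulatory B list had a median of −0.50, below all random lists, with 3 of 18 genes higher and 4 at least 2-fold lower. This median was −0.17 with a pseudocount of 20, −0.83 with a pseudocount of 1 and −0.30 with 1000 UMIs and 500 genes per cell. The lower genes included Cd9, a tetraspanin of regulatory B cells, at −1.62, Prdm1, the driver of plasma cell fate, at −1.60 and Lag3 at −1.42. These cells lay in different clusters in the 2 libraries. With Il10 left out, 3 clusters led by genes such as Cd9, Lag3 and Prdm1 held 13.9%, 12.7% and 4.01% of high-RNA cells in Control and 2.53%, 0.758% and 0.379% in SH-273. Another cluster with Cd9 among its leading genes differed little, with 12.4% in Control and 10.95% in SH-273. Havcr1 (TIM-1) was at −0.96, Tigit at −0.84, Cd274 (PD-L1) at −0.54 and Tgfb1 at −0.06. Pik3cg was at 7.23 CPM against 18.01 and Tmem173 at 12.5 against 12.99. The antigen presentation lists were lower in these cells, with medians of −0.30 for class I, where 0 of 14 genes was higher, and −0.28 for class II, where H2-Eb1 was at −0.74 and H2-Ab1 at −0.70. Mitochondrial transcripts had a median of −0.26 in the same cells. Ccl5 was at 54.8 against 168.7 CPM and Mzb1 and Xbp1, both needed for antibody secretion, at −1.25 and −0.56. Jchain was at −1.70, and this turned to 0.45 with 1000 UMIs and 500 genes per cell. The adaptor Stap1 was at 0.82 and the chromatin organiser Satb1 at 0.52.

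**Figure D2:**
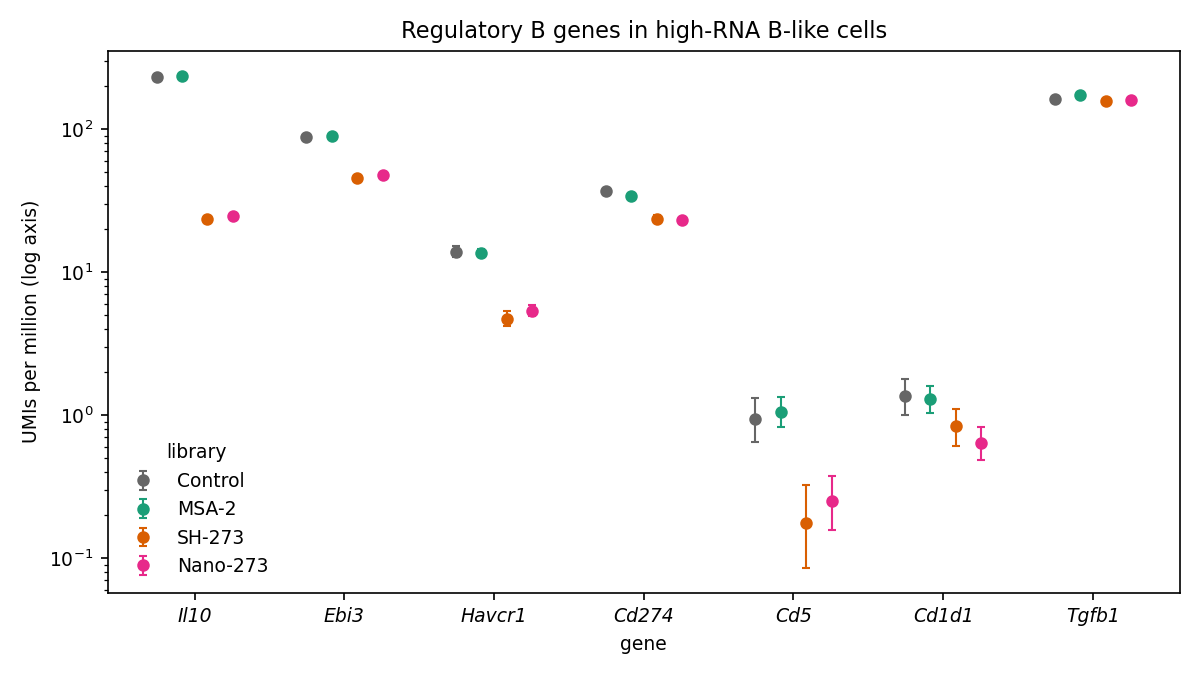
Points give CPM on a log axis for 7 regulatory B genes (horizontal axis) in high-RNA B-like cells of 4 libraries, and bars are 95% Poisson intervals; IPI-549 is left out because it held 5 such cells. Il10 sits near 233 in Control and MSA-2 and near 24 in SH-273 and Nano-273, while Tgfb1 lies between 156.7 and 172.9 in all 4.

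Epithelial-like cells of SH-273 had 14 of 14 MHC class I genes higher, with a median of 1.15. H2-K1 stood at 1052 against 324.8 CPM, H2-D1 at 843.6 against 289.1 and B2m, the light chain of class I, at log2 1.27. The interferon gamma list had a median of 0.82 with 25 of 25 genes higher, class II one of 0.87 with 12 of 12 higher, and type I one of 0.28 with 27 of 32 higher. Ifit1 was at −0.35 and Isg15 at 0.36. Tff1 and Tff2 were at −1.301 and −1.437, and Adm and Vegfa, both induced by low oxygen, at −1.02 and −0.75. Cell cycle genes had a median of 0.35, dissociation stress genes −0.49 and mitochondrial transcripts −0.28. In fibroblast-like cells the class I list had a median of 0.95, Dlk1 stood at 305.9 against 53.2 CPM, and the myofibroblastic list had a median of −0.78 with Acta2, smooth muscle actin, at −1.20.

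Outside the naive clusters, T-like cells of SH-273 had 16 of 18 cytotoxicity genes higher, with a median of 1.05, Gzma at log2 2.55 and Ccl5 at 8901 against 2470 CPM. The regulatory T list had a median of −1.02 with 1 of 12 genes higher, and Foxp3 at −1.01. The cluster led by Nkg7 and Gzma held 383 of these 575 cells, against 85 of 238 in Control. The lists can thus follow the mix of clusters. At resolution 1.0, T-like subclusters led by Foxp3 held 137 and 43 cells in SH-273. They held 120 and 20 in Nano-273 and 5 and 65 in Control. The cluster of regulatory T-like and other CD4-like cells held 155, 113 and 116 in the same order. Some regulatory T-like cells of SH-273 and Nano-273 thus lay in other clusters, which may include the naive ones. In T-like cells outside the naive clusters Ifng was at −0.64, which turned to 0.10 in thinned cells, and Csf2 at −2.81. C1q macrophage-like cells had an interferon gamma median of 0.41, Cxcl9 at 265.8 against 55.4 CPM, and the chemokine Ccl24 at 284.8 against 21.97 CPM. Neutrophil-like cells outside the blood-type clusters had medians of 1.06 for interferon gamma and −0.54 for hypoxia and glycolysis, and the granulocyte factor Csf3 stood at 129.5 against 1.49 CPM. The cDC2-like cells had medians of 0.70 for interferon gamma and −0.46 for class II.

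The comparison of Nano-273 with Control puts the same questions to the nano-formulation. High-RNA and resting B-like cells together filled most of the immune compartment, and epithelial-like, neutrophil-like and macrophage-like shares were the lowest of all 5 libraries. Il10 in high-RNA B-like cells was about as low as in SH-273. Antigen presentation in epithelial-like cells was higher than in Control, and the macrophage/monocyte class was rich in monocyte genes.

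High-RNA B-like cells were 49.7% (48.6 to 50.7) and resting B-like cells 24.3% (23.4 to 25.2) of immune cells. T-like cells were 13.9% (13.2 to 14.6), neutrophil-like cells 5.96% (5.48 to 6.47) and macrophage/monocyte-like cells 2.93% (2.59 to 3.29). Of all kept cells, T-like cells outside the naive clusters were 3.70% in Nano-273 and 3.85% in Control. They were 6.625% in MSA-2, 5.06% in IPI-549 and 6.055% in SH-273. The larger T-like share of Nano-273 thus lay in the naive clusters, at 8.73% of kept cells against 0.582% in Control. In high-RNA B-like cells Il10 stood at 24.8 CPM (23.8 to 25.9) against 232.9 in Control, and UMIs were found in 19.9% of these cells against 72.9%. The share in epithelial-like cells of Nano-273 was 0.811%, at a median depth of 24116 UMIs against 17526 in the B-like cells. After thinning to 1000 UMIs the share was 2.16% (1.76 to 2.63) against 17% in Control. Ebi3 was at 47.6 against 88.1 CPM. The regulatory B list had a median of −0.48 with 4 of 18 genes higher, Cd9 at −1.69, Prdm1 at −1.58, Lag3 at −1.36, Tigit at −0.90 and Tgfb1 at −0.03. The 3 clusters led by genes such as Cd9, Lag3 and Prdm1 held 2.59%, 0.642% and 0.310% of the high-RNA cells here. The other cluster with Cd9 among its leading genes held 9.74% here and 12.4% in Control. Pik3cg was at 7.35 against 18.01 CPM. Class I and class II lists had medians of −0.32 and −0.25, beside −0.23 for mitochondrial transcripts. Mzb1 was at −1.20, Ccl5 at −1.51, Serpinb1a, a protease inhibitor, at 0.76 and Satb1 at 0.51. Jchain was at −1.53 and turned to 0.74 with 1000 UMIs and 500 genes per cell. With that filter the regulatory B median was −0.22, and with pseudocounts of 20 and 1 it was −0.19 and −0.76.

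Epithelial-like cells of Nano-273 had a class I median of 1.23 with 14 of 14 genes higher, H2-K1 at 1129 against 324.8 CPM and H2-D1 at 914.8 against 289.1. The interferon gamma list had a median of 0.87 with 25 of 25 genes higher, class II one of 1.16, and type I one of 0.41. Ido1, which breaks down tryptophan, was at log2 1.65, Gbp2 at 1.87, Tff1 at −1.91 and Ifit1 at −0.34. The largest epithelial-like cluster was another one than in Control, with 195 cells against 171 in the cluster largest in Control. Dissociation stress genes had a median of −0.34. In fibroblast-like cells class I had a median of 1.14, Igfbp3 was at −1.56 and the matrix protein Mgp at −2.36. Among T-like cells outside the naive clusters the cytotoxicity median was 1.08, with Gzma at 3.60 and Gzmb at 967.2 against 294.7 CPM, and the regulatory T median was −0.95. The cluster led by Nkg7 and Gzma held 235 of these 376 cells, against 85 of 238 in Control. The lists can thus follow the mix of clusters here too. C1q macrophage-like cells had 22 of 22 interferon gamma genes higher with a median of 0.99, Cxcl9 at 568.1 against 55.4 CPM and Gbp2 at 2.44. Ly6c2 stood at 604.6 against 41.5 CPM over the macrophage/monocyte class, whose monocyte list had a median of 2.23 with 12 of 12 genes higher. The mix of that class differed. C1q macrophage-like cells were 1.54% of kept cells against 5.74% in Control, and Ly6c2 monocyte-like cells 1.08% against 0.388%. Neutrophil-like cells outside the blood-type clusters had an interferon gamma median of 1.04 and a type I median of 0.58. The Nano-273 values for C1q macrophage-like cells rest on 122 cells and those for fibroblast-like cells on 129.

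**Figure D3:**
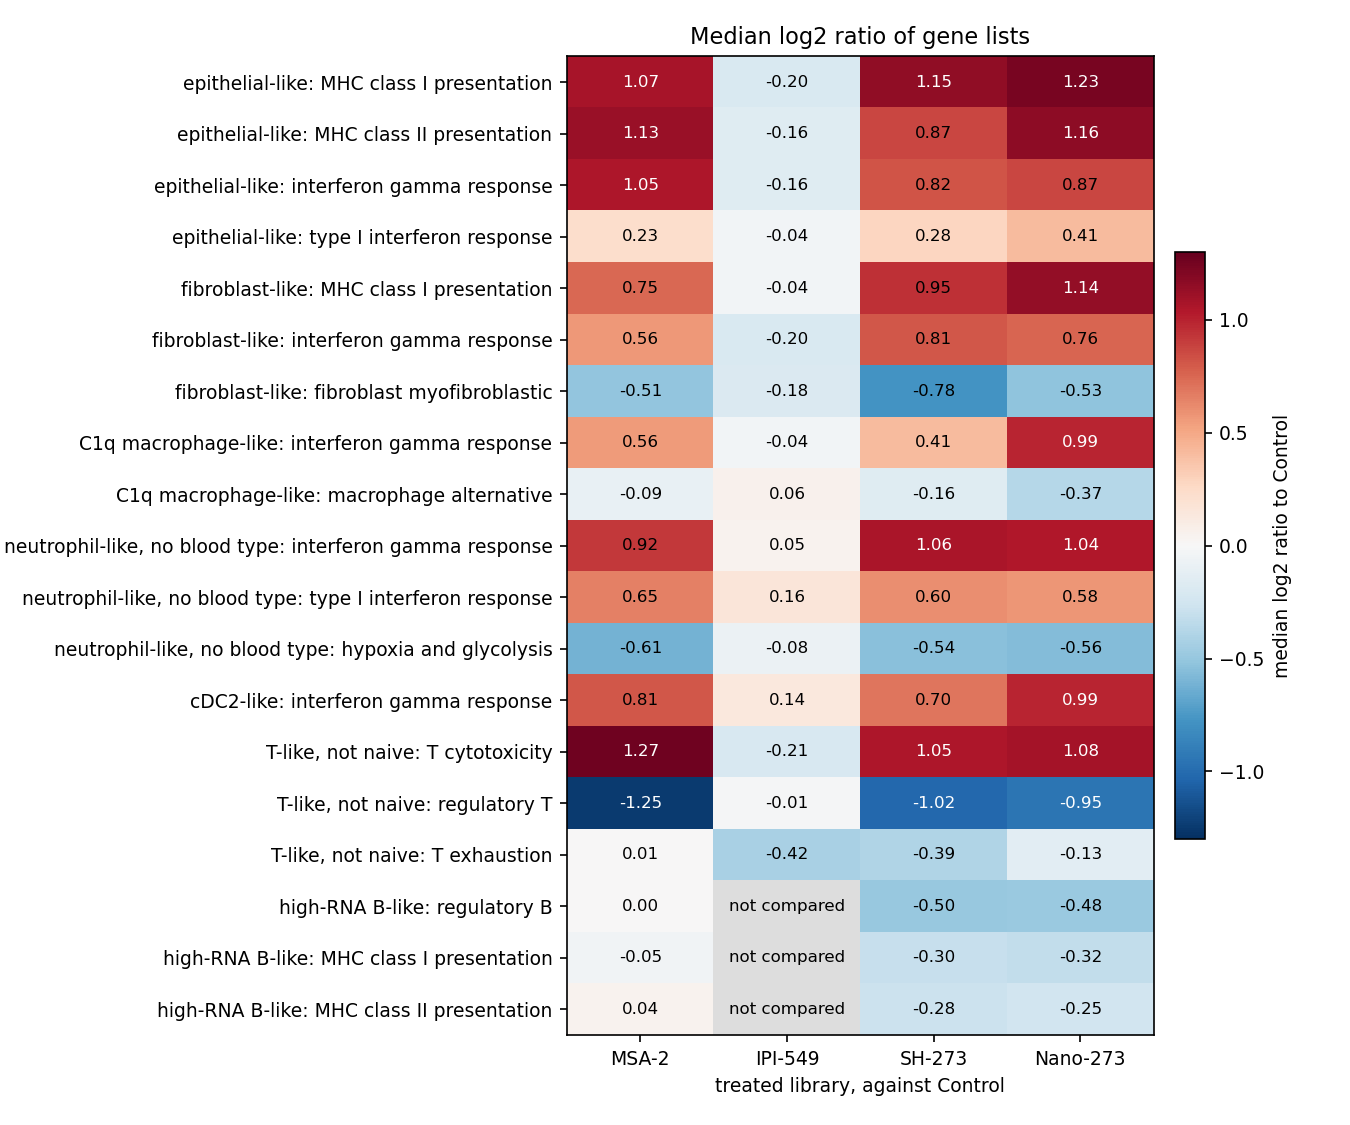
Colours and printed values give the median log2 ratio to Control of 19 pairs of a cell class and a gene list (vertical axis) in the 4 treated libraries (horizontal axis), and grey fields were not compared. MHC class I in epithelial-like cells reads 1.07, −0.20, 1.15 and 1.23 from left to right, and regulatory B genes in high-RNA B-like cells read 0.00 in MSA-2, −0.50 in SH-273 and −0.48 in Nano-273.

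SH-273 against MSA-2 sets the compound read as aimed at both targets beside a STING agonist. These are different molecules at doses not given, with 1 library each, so the part of a second target cannot be told apart. The clearest difference was in high-RNA B-like cells, where Il10 was at 23.5 against 234.3 CPM, a log2 ratio of −3.07, and Ebi3 at −0.90. The 3 clusters led by genes such as Cd9, Lag3 and Prdm1 held 15.2%, 11.96% and 5.66% of high-RNA cells in MSA-2 and 2.53%, 0.758% and 0.379% in SH-273, so the cells lay in different clusters here too. The other cluster with Cd9 among its leading genes held 12.5% in MSA-2 and 10.95% in SH-273. The regulatory B list had a median of −0.45 with 2 of 18 genes higher in SH-273, and Pik3cg was at −1.02. Mt1 was at 40.5 against 141.3 CPM, the signalling regulator Rgs2 at 0.55 and Stap1 at 0.85. Resting B-like cells had a regulatory B median of 0.05, and the protease inhibitor Slpi was at 0.68 there. In the whole B-like class Ltb was at 1.71, Ms4a1 (CD20) at 1.12 and Tmcc3 at −0.84, beside a resting share of 30.5% against 13.95% of immune cells.

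In epithelial-like cells the class I list had a median of 0.02 and the interferon gamma list −0.14. In T-like cells without the naive clusters the regulatory T list had a median of 0.07. In C1q macrophage-like cells the interferon gamma list had a median of −0.29, Ccl24 was at 1.60, Gpnmb at 1.12, Ccl5 at −1.75 and the platelet chemokine Ppbp at −2.47. Over the whole macrophage/monocyte class Hpgd, which breaks down prostaglandins, was at 1.26 and Mfge8 at −2.54.

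SH-273 against IPI-549 sets the same compound beside a PI3Kγ inhibitor, and the part of a single target cannot be told apart here either. SH-273 had the high-RNA B-like block, 29.99% against 0.165% of immune cells, and IPI-549 more neutrophil-like cells, 30.1% against 9.46%. In the whole B-like class Rgcc was at 352.6 against 4.60 CPM, Zbtb32 at 263.1 against 2.45 CPM, Fcer2a at −3.32 and Cd55, a complement inhibitor, at −3.22. Il10 was at 21.2 CPM in SH-273 and had 0 UMIs in IPI-549. Resting B-like cells differed little, with a regulatory B median of 0.16, and Slpi was the highest gene there under the rule for named genes.

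Epithelial-like cells had a class I median of 1.37 and an interferon gamma median of 0.96 in SH-273 against IPI-549. T-like cells without the naive clusters had a cytotoxicity median of 1.20. The cluster led by Nkg7 and Gzma held 383 of 575 of these cells in SH-273 and 59 of 231 in IPI-549. C1q macrophage-like cells had Cxcl9 at 265.8 against 60.9 CPM and Ccl24 at 284.8 against 81.3 CPM, with an alternative activation median of −0.31. Their Ctsk was at 99.6 against 171.1 CPM, a smaller gap than the 42.8 against 143.9 CPM over the whole macrophage/monocyte class.

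Nano-273 against SH-273 sets the library read as the nano-formulation beside that of the compound. With 1 library each an effect of the formulation cannot be told from a difference between animals. High-RNA B-like cells held a larger share of immune cells in Nano-273, 49.7% against 29.99%, and resting B-like cells a smaller one, 24.3% against 30.5%. Among immune cells without the high-RNA block the resting share turned, to 48.3% (46.8 to 49.7) in Nano-273 against 43.5% (42.2 to 44.9) in SH-273. Inside the high-RNA block the libraries were close, with Il10 at log2 0.07, Ebi3 at 0.06 and Pik3cg at 0.01. Under the rule for named genes the furthest there were Tuba1b at 0.17, Odc1 at 0.16, the replication helicase subunit Mcm5 at 0.15, Gapdh at −0.22 and Bcl2a1d at −0.21. Epithelial-like cells had class I and interferon gamma medians of 0.04 and 0.00. T-like cells without the naive clusters had medians of 0.05 for cytotoxicity and −0.06 for regulatory T genes. C1q macrophage-like cells were further apart, with an interferon gamma median of 0.68, Inhba, a subunit of activin, at 2.87, Ccl7 at 1.54 and Lpl, a lipase, at −1.55. Over the whole macrophage/monocyte class Ly6c2 was at 604.6 against 263.2 CPM. The mix of that class differed, with C1q macrophage-like cells at 1.54% against 2.69% of kept cells. Ly6c2 monocyte-like cells came at 4.98 against 5.26 per 100 resting B-like cells. Slpi in resting B-like cells was at 0.97, and this turned to −0.20 with 1000 UMIs and 500 genes per cell.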

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

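The barcodes described first were examined only after the libraries had been seen. The tests of B-1a-type cells, of the mix of states, of blood and of RNA in empty droplets were fixed before their results were seen, and those of spleen, of the reweighted clusters and of the small clusters after.

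Barcodes with at least 1000 antibody UMIs and fewer than 500 gene UMIs, which no comparison used, numbered 840 in Control. They numbered 1487 in MSA-2, 2797 in IPI-549, 2705 in SH-273 and 1721 in Nano-273, and stood out as a signal outside the gene data above the Control count. As a share of antibody UMIs these barcodes were highest in Control, with 17.2% against 13.3%, 11.1%, 13.6% and 12.7%. Cluster 26, which had no name and was led by collagen genes, had a median of 67269 antibody UMIs per cell in MSA-2 (161 cells) against 304.5 in Control (18 cells). The median over all cells of MSA-2 was 515.

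Il10 was lower in high-RNA B-like cells of SH-273 and Nano-273 than in Control. A loss of B-1a-type cells, marked here by Ighv11-2, could contribute, since these were 3.87% of the high-RNA cells in Control, 0.21% in SH-273 and 0.27% in Nano-273. Among Ighv11-2 cells the log2 ratio of Il10 was −1.50 at its highest, from 5 cells in SH-273 and 12 in Nano-273. Resting B-like cells carried Ighv11-2 in 0.54% and 0.32% of cells in these 2 libraries, so the 5 and 12 cells may be background. High-RNA cells without Ighv11-2 had ratios of −3.001 and −2.944, so loss of the marked cells is not the main part and the part of B-1a cells without Ighv11-2 stays open. Another mix of states could hold a part. Weighting clusters made without Il10 as in Control took the ratio from −3.06 to −1.76 in SH-273 and from −2.99 to −1.72 in Nano-273. Another mix of these clusters is excluded as the whole, while finer states inside a cluster stay open. The highest ratio within a cluster of at least 50 cells in both libraries was −1.757, which lay between the limits set in advance and cannot tell. A smaller cluster with 57 cells in Control had −0.62 from 9 cells in SH-273 and −0.58 from 14 in Nano-273. A direct effect of the treatment on the gene is the biological alternative, and 1 library per group cannot separate it from a difference between animals.

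Resting B-like and naive T-like cells took larger shares in every treated library. Spleen taken with the tumor fits, because a marginal zone-like cluster with high Cr2 and Cd1d1, a cell of the spleen, made up at least 8.55% of resting B-like cells in each treated library. In Control 0 of 29 allows up to 11.94%, so this share does not set the treated libraries apart. Red pulp macrophage genes, given under the other observations, pointed both ways. Blood in the tumor also fits, with haemoglobin in the empty droplets at a log2 ratio of at least 2.39 to Control, though blood alone would not bring the marginal zone-like cells. The naive T-like cells came at 42.4, 38.3, 39.7 and 40.2 per 100 resting B-like cells in MSA-2, IPI-549, SH-273 and Nano-273, a nearly fixed ratio. Control had 124.1, from 36 naive T-like and 29 resting B-like cells. Whole main clusters were counted here, among them a cluster led by Cd8b1. The naive subset given under the other observations holds fewer cells. Entry of resting lymphocytes into the tumor is the biological alternative and was not tested apart from these.

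High-RNA B-like cells were nearly missing from the IPI-549 library. Loss of captured cells by lysis is excluded as the cause. In the empty droplets of IPI-549, 4 genes of these cells stood at 4.77% (3.39 to 6.52) of the median of the other libraries. Those droplets held fewer than 100 UMIs, so the value does not cover cells removed by the filters. The mitochondrial limit removed 43 barcodes of this library and the doublet call 4. Removal before capture, another tumor site or a treatment effect may each account for it, and the value of 4.77% does not tell them apart.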

How the results depend on the processing

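Of the alternatives, 33 were planned and 10 were chosen after seeing the data, namely Il10 left out of the clustering, clusters of high doublet score kept, the 6% of cells with the highest doublet scores removed, the parts of classes taken alone and the first naming rule of subsets. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Of 440 class shares 250 stayed within their interval and 190 moved. Of 352 directions of a treated share against Control 318 were kept, 10 turned and 24 were lost because both shares were 0. Of 2268 values of gene lists 1969 were the same, 287 moved and 12 reversed, and of 5256 values of genes 4513, 712 and 31. Of 208 shares of cells with a UMI 188 moved under thinning, which lowers every share by its construction, and 36 of 125 subset shares moved. Cells kept moved in 5 of 10 cases, all under the 99th percentile calling, which called 3816, 3323, 1535, 3628 and 5001 cells before doublets were removed. Shares under this calling are those of deep cells, since most cells of the shallow classes were left out. With doublets kept, high-RNA B-like cells gave no values because their clusters had no name. TMM factors reversed 0 of 230 lists. Where no cause is given, the cause was not tested.

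The share of high-RNA B-like cells depends on naming. With doublets kept, a mitochondrial maximum of 10% or a resolution of 0.5 it was 0 in all libraries, because 99.71%, 99.69% and 99.98% of these cells fell in clusters without a name. In the order Control, MSA-2, IPI-549, SH-273 and Nano-273, resolution 2.0 gave 27.96%, 33.75%, 0.0332%, 23.97% and 43.1%. The 99th percentile calling gave 43.8%, 48.5%, 0, 74.6% and 83.8%, and a class per cell from markers 4.79%, 7.66%, 0.520%, 5.63% and 7.71%. With 1000 UMIs and 500 genes it was 34.4% in Control, 40.2% in MSA-2 and 50.97% in Nano-273. Of these cells 8.91% were then named plasma-like. The plasma-like share was uneven, at 19.63% in Control, 21.97% in MSA-2, 2.232% in SH-273 and 2.258% in Nano-273. Jchain and the regulatory B list under this filter therefore left out more high-RNA cells of Control and MSA-2. In the same order the 99th percentile calling named 32.79%, 33.25%, 4% and 3.696% plasma-like. It left 19.63%, 19.67%, 36.72% and 34.24% in clusters without a name. Directions turned for high-RNA B-like cells of SH-273 under the 99th percentile calling and the class per cell, with 74.6% against 43.8% and 5.63% against 4.79% in Control. With the 99th percentile calling T-like cells turned in MSA-2 (1.88% against 2.84%), and epithelial-like (72.4% against 49.6%) and macrophage/monocyte-like cells (41.4% against 11.9%) in IPI-549. The cDC2-like share of IPI-549, 2.80% against 2.49%, turned under 5 settings, with values between 2.29% and 3.14% against 2.505% to 4.58%.

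Il10 in high-RNA B-like cells of SH-273 had log2 ratios of −2.89 with 1000 UMIs and 500 genes, −3.25 with pseudocount 1, −2.54 with pseudocount 20 and −3.62 thinned. In Nano-273 it had −2.84, −3.18 and −2.50 under the first 3 of these. In MSA-2 it was −0.033 with Il10 left out of the clustering and −0.16 thinned. The regulatory B list in SH-273 was −0.30 with 1000 UMIs and 500 genes, −0.40 with Il10 left out, −0.34 with a minimum of 1 UMI, −0.83 and −0.17 with pseudocounts 1 and 20, and −0.34 thinned. In Nano-273 it was −0.22 with 1000 UMIs and 500 genes, −0.70 without genes under the empty droplets, −0.39 and −0.57 with minimums of 1 and 100 UMIs, −0.76 and −0.19 with pseudocounts 1 and 20, and −0.40 thinned. In MSA-2 it was 0.069 thinned.

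MHC class I in epithelial-like cells was 1.33 and 0.76 in MSA-2, 1.40 and 0.75 in SH-273, 1.42 and 0.77 in Nano-273 and −0.28 and −0.13 in IPI-549 with pseudocounts 1 and 20. Without genes under the empty droplets it was 0.90 in SH-273 and 1.37 in Nano-273. In IPI-549 it was −0.29 with doublets kept and −0.31 thinned. T cytotoxicity without the naive clusters was 1.03 in MSA-2 with pseudocount 20, 1.296 in Nano-273 with a minimum of 100 UMIs, and 1.49, −0.43, 1.29 and 1.39 thinned in MSA-2, IPI-549, SH-273 and Nano-273.

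Signs turned as follows. With 1000 UMIs and 500 genes, Jchain in high-RNA B-like cells was 1.13 in MSA-2, 0.45 in SH-273 and 0.74 in Nano-273, Ccl5 −0.089, Mzb1 −0.15 and Pik3cg −0.079 in MSA-2, and the cell cycle list 0.0029 in Nano-273. In resting B-like cells of Nano-273 against SH-273, the same filter gave −0.20 for Slpi, 0.033 for the regulatory B list and −0.013 for the type I list. A minimum of 100 UMIs gave 0.0016 for that regulatory B list. With Il10 left out, Ccl5 was −0.015 and H2-Ab1 −0.0010 in high-RNA B-like cells of MSA-2. Thinned, Ccl5 was −0.16, Pik3cg −0.020, Cd274 0.16 and the MHC class II list −0.079 in the same cells. Thinned T-like cells without the naive clusters had Cxcl10 at −0.14 and the naive list at −0.20 in IPI-549, and Ifng at 0.10 in SH-273. Thinned, Ifit1 was 0.80 in epithelial-like cells of IPI-549, and the regulatory B list −0.039 in resting B-like cells of SH-273 against IPI-549. With doublets kept, Isg15 was 0.079 in epithelial-like cells of MSA-2, Slpi −0.17 in resting B-like cells of Nano-273 against SH-273, and the T-like cell cycle list −0.0099 in Nano-273.

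Values of whole classes turned where a part was taken alone, which follows from the mix of cells. In high-RNA B-like cells alone Cd79b was −0.075 in MSA-2 and −0.011 in Nano-273, and the naive follicular list −0.048 in Nano-273. Without the blood-type clusters Ltf was −0.18, −0.44 and −0.11 and Ngp −0.74, −0.66 and −1.91 in MSA-2, SH-273 and Nano-273. Without the naive T-like clusters Tcf7 was −0.35, −0.083, −0.43 and −0.43 in the treated libraries, Nsg2 −0.23 in SH-273 and −0.64 in Nano-273, the naive list −0.077 in MSA-2 and −0.22 in Nano-273, and the exhaustion list 0.0091 in MSA-2. Depth limits the thinned values, which leave out cells under 1000 UMIs.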

Other observations

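The subsets and antibody genes given here were examined after the class shares had been seen, and no explanation of them was tested.

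The resting cells of the treated libraries had a common make-up. Naive T-like cells were 9.49% of T-like cells in Control, 30.9% in MSA-2, 49.1% in IPI-549, 48.7% in SH-273 and 55.3% in Nano-273. At resolution 0.5 these shares were 4.01%, 13.3%, 20.1%, 22.6% and 25.5%. They leave out a cluster without a name whose highest marker score was the naive one. It held 13, 131, 189, 441 and 419 T-like cells in the same order. In the whole T-like class Lef1, a factor of naive T cells, had log2 ratios to Control of 1.53, 1.99, 1.92 and 1.99, and Tcf7 0.95, 1.34, 1.16 and 1.44. Dapl1 was the highest gene of the class in all 4 under the rule for named genes, between 2.03 and 2.67. Regulatory T-like cells were 25.5% of T-like cells in Control and 9.76%, 20.3%, 11.7% and 11.1% in the treated libraries. At resolution 0.5 they were 23.7% in Control and 4.14%, 8.40%, 2.74% and 1.504% in the others. These lower values leave out a cluster led by Foxp3 that had no name at that resolution. It held 6 T-like cells in Control, 40 in MSA-2, 73 in IPI-549, 142 in SH-273 and 121 in Nano-273. For every 100 resting B-like cells there were 7.81, 7.64, 7.87 and 7.74 Retnlg neutrophil-like cells and 5.67, 4.79, 5.26 and 4.98 Ly6c2 monocyte-like cells. Control held 29 resting B-like cells, 0 of them marginal zone-like, which allows a share of up to 11.94%. Erythroid progenitor genes in the empty droplets had log2 ratios to Control of 0.55, 3.50, 3.14 and 1.85. A macrophage subcluster led by Hba-a1, with Itgad, Cd5l and Slc40a1 of red pulp macrophages, held 0 cells in Control and 5, 10, 16 and 19 in the treated libraries. The red pulp macrophage list had log2 ratios of −1.41, 0.21, −1.16 and −2.49 in the empty droplets, where most of its UMIs were Vcam1. Its members Spic and Cd5l had 0 UMIs there in Control and MSA-2, and between 1 and 4 in each other library. Over macrophage/monocyte-like cells the interval of the list was 103.6 to 127.2 CPM in Control, and its level 166.2, 165, 178.3 and 270.8 CPM in the treated libraries.

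Camp and Ngp, granule genes of immature neutrophils, were higher over the neutrophil-like class in the treated libraries. A cluster of few cells was led by them, though in IPI-549 Ngp was also higher outside the blood-type clusters. Camp, an antimicrobial peptide, stood at 1.11 CPM in Control, from 3 UMIs, and at 1580, 612.5, 2991 and 7289 CPM in MSA-2, IPI-549, SH-273 and Nano-273. The pseudocount sets the size of its log2 ratios, which were 8.02, 6.66, 8.94 and 10.22. Ngp had 5.73, 4.60, 6.60 and 7.97, and outside the blood-type clusters −0.74, 1.52, −0.66 and −1.91. The cluster that carries them held 0 cells in Control, 8 in MSA-2, 5 in IPI-549, 25 in SH-273 and 28 in Nano-273. Monocyte-like cells were 11.3% of the macrophage/monocyte class in Control, 17.9% in MSA-2, 15.3% in IPI-549, 27.0% in SH-273 and 33.5% in Nano-273. Under the first naming rule they were 28.8%, 31.7%, 31.6%, 36.7% and 44.4%, and at resolution 0.5 20.6%, 29.5%, 23.9%, 33.8% and 36.1%.

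Antibody variable genes differed inside the high-RNA B-like block. Ighv11-2, known from B-1a cells, was seen in 3.87% (2.93 to 5.01) of cells in Control and 4.90% (4.06 to 5.85) in MSA-2. Igkv14-126, its usual light chain partner, was seen in 4.996%, 6.73%, 1.26% and 1.15% of cells in Control, MSA-2, SH-273 and Nano-273. Igkv4-91, a light chain gene of other B-1a cells, was seen in 1.20%, 1.58%, 0.968% and 1.24%. Its usual heavy chain partner Ighv12-3 was seen in 1.196%, 1.70%, 0.379% and 0.332%, from 17, 40, 9 and 15 cells. The intervals of Control (0.698 to 1.91) and SH-273 (0.173 to 0.718) overlap slightly, while that of Nano-273 (0.186 to 0.547) lies below Control. Of heavy chain variable gene UMIs Ighv12-3 made up 1.005%, 4.69%, 3.24% and 2.02%. This share also rises where the total of these UMIs falls, as in SH-273 and Nano-273. Of all UMIs of the high-RNA cells it had 461 of 36256839, 3684 of 66970692, 429 of 56402732 and 514 of 92135272. By that measure it was lower in SH-273 and Nano-273 than in Control, as in the shares of cells. All heavy chain variable genes together had 1265, 1173, 234.7 and 276.7 CPM. Ighv1-26, a gene of no such bias, was seen in 4.93%, 5.24%, 5.01% and 4.87%.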
